A study of Homo sapiens with 2 samples.

How the data were processed

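Droplet libraries (10x Genomics Chromium, 3' chemistry) were made from 1 culture of SK-N-BE(2)-C cells with doxycycline and 1 without, per the labels. The submitters' processing notes name kallisto and bustools; versions, genome build and annotation are not given in the sources used here. The deposited table holds counts, whole numbers of molecules per gene and cell, for 36027 genes and 1622 cells, and 70 genes had no count in any cell. The deposited annotation of cells gives the type of each cell, control or induced, per the file headers, and cells were assigned to libraries through it. It also gives the percent of mitochondrial counts per cell as the authors computed it, at most 20.0 in any cell, and marks all 1622 cells as singlets. How doublets and low-quality cells were removed is not given in the sources used here. The column sums of the table were checked against the annotated totals and differed by at most 192 counts. Gene symbols were taken from the authors' own table, in which 376 rows repeat a symbol. Reads that fit several genes can be lost or split by such counting, so the levels of genes with near-identical copies, ribosomal protein genes and LDHA among them, are uncertain, as is that of TH. No genome coordinates are given because the files name no build.

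Counts were summed over the cells of each library and scaled by the library total to CPM. Log2 ratios are of the induced over the control library with a pseudocount of 1 CPM, which understates the difference of low genes, and genes with at least 10 CPM in either library were called measured. No test was run across cells, which are not replicates. Sums have exact Poisson intervals, ratios of sums exact conditional intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and for counting error only. Intervals of a list median are order-statistic intervals over its genes, at 95% or more from 6 genes up and the plain range below that. A count of 0 would allow up to 3 counts, which is 0.0373 CPM in the induced and 0.0315 CPM in the control library. The 28 gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule names HRAS and other RAS genes, the 12 genes with the highest and the 12 with the lowest log2 ratio among genes with at least 25 CPM in either library and a symbol that is not clone-based, and the 2 highest and 2 lowest measured members of each list. FN1, S100A10, DUSP6, SHC1, TH, LDHA and PRRX1 were named after their values were seen. Some genes that the rule names are not reported here. A gene in several lists counts in each. For the 23 lists with at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Random lists do not keep the tendency of related genes to shift together. A list whose members do so can reach an extreme percentile with a small shift, so percentiles are descriptive and test no difference.

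For values per cell, each cell was thinned at random to 53000 counts, the largest multiple of 1000 that kept at least 80% of the cells of each library. This left out 104 induced and 190 control cells. Phases were scored with scanpy 1.11.5. Clusters were found by the Leiden method (igraph 0.11.9) on 2000 variable genes, 30 principal components and 15 neighbours at a resolution of 0.5. Scaling factors came from edgeR 4.0.16 and DESeq2 1.42.0, which were used for no test. On simulated data with 200 genes changed 3-fold in an induced against control comparison of 8588 genes, 100 of 100 genes made higher and 100 of 100 made lower passed 2-fold, as did 0 of 8388 unchanged genes. The simulated counts held Poisson error only, with no variation between cells, cultures or libraries. They check the calculation and give no rate of false calls for the real comparison.

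Alternatives fixed in advance were TMM and DESeq2 scaling, totals without ribosomal protein and mitochondrial genes, the mean of per-cell CPM, leaving out the 5% of cells with the most or the 20% with the fewest counts, thinning, pseudocounts of 0.1 and 5 CPM, no filter beyond 1 count, a filter at 50 CPM, other thinning depths, and other clustering settings. A limit on mitochondrial percent and MALAT1, leaving out the cluster with the highest summed CPM of the endothelial marker list, and wider HRAS bins were chosen after seeing the data.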

Results

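Single-cell RNA sequencing was carried out on SK-N-BE(2)-C cells, an established human neuroblastoma line, that carried a doxycycline-inducible gene for HRASV12, a mutant form of the small GTPase HRAS that stays in its active state. 1 library came from cells given doxycycline at 100 ng/ml for 13 days (the HRASV12 induced library) and 1 from untreated cells (the uninduced control library). The induced library held 666 cells and 80359736 counts, with a median of 111582 counts per cell. The control library held 956 cells and 95350640 counts, with a median of 85821 per cell. With 1 library per group there was no replicate check and no test, so every difference describes these 2 libraries. Intervals of levels, ratios and shares of cells are 95% intervals that cover counting error only. The induced library reached lower in 2 measures per cell: the 5th percentile of the mitochondrial percent was 1.44 in induced and 8.52 in control cells, and that of the nuclear RNA MALAT1 was 33.6 against 238 CPM. Whether cells low in these measures were of poor quality was not tested.

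The first question was whether HRAS itself differed. HRAS (ENSG00000174775.17) stood at 161 CPM (counts scaled to the library total) in the induced and 109 CPM in the control library, a ratio of 1.47 (exact interval 1.43 to 1.51, from 12911 and 10433 counts). NRAS, a close relative, had a ratio of 1.22 (1.17 to 1.27). With every cell thinned to 53000 counts, 99.3% of 562 induced cells (Clopper-Pearson interval 98.2 to 99.8) and 99.1% of 766 control cells (98.1 to 99.6) had at least 1 HRAS count, and the unthinned shares were 98.0% and 98.5%. At least 10 HRAS counts were found in 32.4% of induced cells (28.5 to 36.4) and in 9.92% of control cells (7.90 to 12.3). The median was 8 HRAS counts per cell in the induced and 5 in the control library. Counting at the 3' end does not tell transgene from native transcripts and misses a transgene that lacks the native 3' end, so the ratio is not a measure of the induced protein.

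Among genes with at least 25 CPM in either library, ANKRD1, TM4SF1, LRRC17 and ACTA2 had the highest log2 ratios of induced over control, and CARTPT, FOSB, IGDCC3 and LHX9 had the lowest. VIM, the intermediate filament vimentin, stood at 1510 CPM in the induced and 182 CPM in the control library, a ratio of 8.27 (8.14 to 8.41). TNFRSF12A, a TNF receptor family member, stood at 135 against 11.9 CPM, and ACTA2, smooth muscle actin, at 71.2 against 4.07 CPM. ANKRD1, a YAP target, had 2257 counts against 15, a log2 ratio of 4.65, which was 3.18 with both libraries limited to cells at or above the control library's 5th percentile of mitochondrial percent and MALAT1, a setting chosen after seeing the data. Also among the 12 highest were TM4SF1, LRRC17, TSPAN8, PRSS23, STMN4, SNCG and PLPP4, with log2 ratios from 2.99 to 4.25. At the other end, CARTPT, a neuropeptide precursor, stood at 0.896 CPM in the induced and 45.6 CPM in the control library. Its counts were concentrated in 1 cluster of 140 control and 6 induced cells, at 185 CPM against 4.67 CPM in all other cells. FOS stood at 41.9 against 158 CPM and FOSB at 4.87 against 28.9 CPM. DLK1, a marker of chromaffin cells, stood at 459 against 1370 CPM. IGDCC3, LHX9, BTG2, SERINC5, IGF2, HIST1H1B, HIST1H1D and SEMA6A completed the 12 lowest, with log2 ratios from -2.11 to -1.43. Of 9017 genes with at least 10 CPM in either library, 362 were at least 2-fold higher and 114 at least 2-fold lower in the induced library, so that 76.1% of these genes were on the higher side. That share was 87.5% with TMM scaling (457 higher, 65 lower), 91.5% with DESeq2 size factors (509 and 47) and 63.0% with totals that left out ribosomal protein and mitochondrial genes (360 and 211).

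Targets of MAPK signalling were higher in the induced library. Of 18 measured genes of this list, 11 were at least 1.5-fold higher and 1 was at least 1.5-fold lower, with a median log2 ratio of 0.82, at the 100th percentile of 10000 random lists matched on expression. Such percentiles are descriptive, since genes that shift together reach an extreme one even with a small shift. PLAUR, the urokinase receptor, stood at 19.3 against 2.76 CPM (log2 ratio 2.43, and 1.78 without the 70 cells described below), and HBEGF, a growth factor for the EGF receptor, at 22.9 against 4.17 CPM. DUSP6, a phosphatase of ERK, stood at 20.6 against 4.42 CPM. ETV1 was near level (15.7 against 16.0 CPM), and EGR1, an immediate-early transcription factor, stood at 74.6 against 146 CPM. The AP-1 family, which pairs FOS and JUN proteins, was split: 2 of 10 measured members were at least 1.5-fold higher and 2 at least 1.5-fold lower (median -0.05, 44.7th percentile, and -0.36 with the limit on mitochondrial percent and MALAT1). FOSL1 and FOSL2 were the highest, FOS and FOSB the lowest. The log2 ratio of FOSL2 was 0.64, and 0.54 without the 70 cells described below, where 1 member was higher and 3 were lower by 1.5-fold. Components of the RAS pathway had a median of 0.01 (66.9th percentile), with 3 of 18 at least 1.5-fold higher, namely RASSF1, RRAS and SHC1. Only RASSF1 passed 1.5-fold with the limit on mitochondrial percent and MALAT1, where the log2 ratio of RRAS was 0.58 and that of SHC1 0.53, and SHC1 did not pass without the 70 cells described below (0.55).

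Mesenchymal genes were higher in the induced library, most of all those of the surface, cytoskeleton and matrix. Of 24 measured surface and cytoskeletal genes, 18 were at least 1.5-fold higher and 0 at least 1.5-fold lower (median 1.26, 100th percentile). S100A10 stood at 2078 against 286 CPM. ANXA1, a membrane-binding annexin, stood at 21.0 against 0.0944 CPM, but 92.1% of its induced counts came from 178 induced cells of 1 cluster with a median mitochondrial percent of 6.70 and MALAT1 at 948 CPM, and its log2 ratio of 4.33 was 2.49 with the limit on mitochondrial percent and MALAT1. Of the induced ANKRD1 counts 82.8% came from the same induced cells. The cells of that cluster had a median of 148831 counts, against 111582 over all induced cells, so they were not short of counts. With the limit on mitochondrial percent and MALAT1 the log2 ratio of CCN2 was 2.74 against 3.38 in all cells and that of FOSL1 1.28 against 2.13. CALD1 and S100A4 were the lowest, at 118 against 147 CPM and 132 against 153 CPM. Of 11 matrix genes, 6 were at least 1.5-fold higher and 0 lower by that size (median 1.33, 100th percentile), with CCN2 among the highest and COL6A1 and LAMB1 lowest. Fibronectin, FN1, stood at 79.9 against 14.2 CPM. The mesenchymal transcription factors moved less: 6 of 18 were at least 1.5-fold higher and 0 lower by that size (median 0.15, 93.4th percentile). The list holds 37 factors, and the rest were under the 10 CPM floor, among them PRRX1, with 20 against 52 counts. With no filter on low genes, 9 of 37 were higher and 0 lower by that size (median 0.07). IFI16 stood at 24.7 against 0.430 CPM and FOSL1 at 14.7 against 2.60 CPM, while ID3 and AEBP1 were lowest. With the limit on mitochondrial percent and MALAT1, the surface and cytoskeletal median was 0.86 over 22 genes, no longer with ANXA1. The matrix median depended on few cells: without the 70 cells of the cluster highest in the endothelial marker list (535 CPM, against at most 203 CPM in any other cluster), also a setting chosen after seeing the data, it was 0.46. It then covered 8 measured genes, 4 of them at least 1.5-fold higher, so the 2 matrix medians are not of the same genes. Without those cells the log2 ratio of FN1 was 1.91 against 2.41 in all cells and that of LRRC17 3.13 against 4.09, and the median of the mesenchymal transcription factors turned to -0.05, with 4 of 17 higher and 1 lower by 1.5-fold. That median was -0.31 over the 4 genes of at least 50 CPM, of which 1 was higher and 0 lower by 1.5-fold. The matrix median was 0.67 with no filter on low genes.

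**Figure D1:**
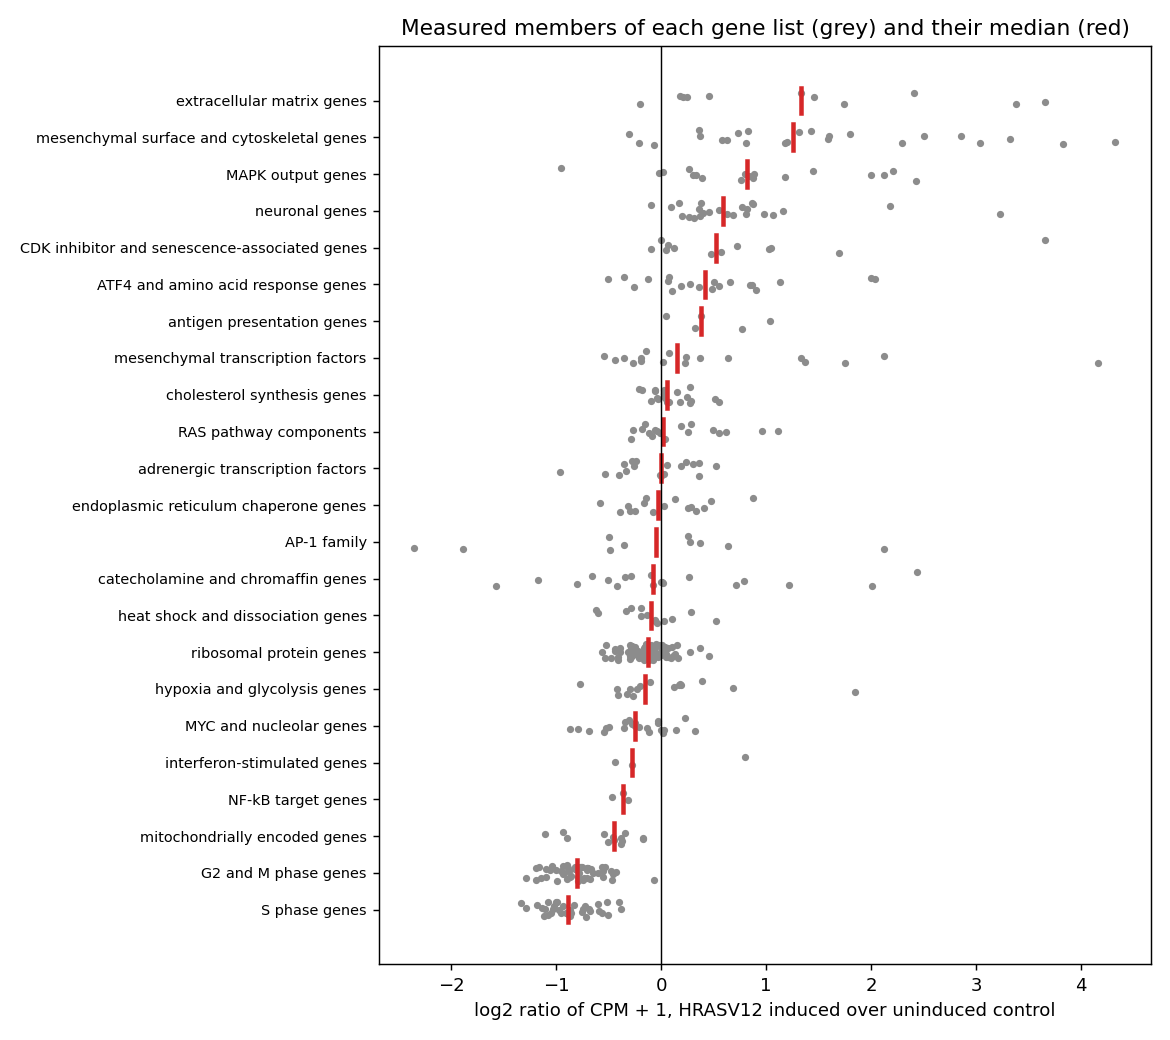
Log2 ratio of CPM + 1 between the HRASV12 induced and uninduced control library (x axis) for each measured member (grey points) of 23 gene lists (y axis), with the list median as a red bar. The medians run from -0.88 for S phase genes to 1.33 for extracellular matrix genes.

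Transcription factors of the adrenergic identity stayed level as a group while single neuroendocrine genes differed both ways. Of 18 measured adrenergic factors, 0 were at least 1.5-fold higher and 1 was at least 1.5-fold lower (median 0.00, 49.0th percentile of the random lists, and between -0.25 and 0.16 over the alternatives). With the limit on mitochondrial percent and MALAT1, 2 were higher and 1 was lower by that size. HAND2, which did not pass 1.5-fold, stood at 172 against 250 CPM, and ISL1 and KLF7 were the highest. TH, the first enzyme of catecholamine synthesis, was under the 10 CPM floor in both libraries, with 92 against 345 counts (ratio 0.316, 0.249 to 0.399), and its level is uncertain because reads lost in counting were not ruled out. Among 19 catecholamine and chromaffin genes, 5 were at least 1.5-fold higher and 4 at least 1.5-fold lower (median -0.08, 23.6th percentile, and 0.08 with DESeq2 size factors and 0.09 with the limit on mitochondrial percent and MALAT1). SCG5, a secretory granule protein, stood at 84.6 against 20.2 CPM. CHGA, chromogranin A, stood at 446 against 1004 CPM. Neuronal genes were higher in the induced library: 12 of 24 by at least 1.5-fold and 0 lower by that size (median 0.59, 100th percentile). STMN4 and TAGLN3 were the highest and KIF1A and MAP2 the lowest.

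The differences in MAPK output and mesenchymal genes ran through most induced cells but not all of them. At equal depth, 90.9% of 562 induced cells (88.2 to 93.2) lay above the control median for MAPK output genes and 45.7% (41.6 to 49.95) above the control 95th percentile. For the joined mesenchymal lists these shares were 87.9% (84.9 to 90.5) and 63.3% (59.2 to 67.3), so that 206 induced cells were not above the control 95th percentile. For the joined adrenergic lists they were 39.0% (34.9 to 43.1) and 5.52% (3.78 to 7.74), and without DLK1 the first was 54.8%. By a measure chosen after seeing the data, 18.9% of induced cells (15.7 to 22.3) lay below the control 5th percentile, and 13.7% without DLK1. The median induced cell had 142 mesenchymal counts per 10000, against 63.5 in the control library.

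**Figure D2:**
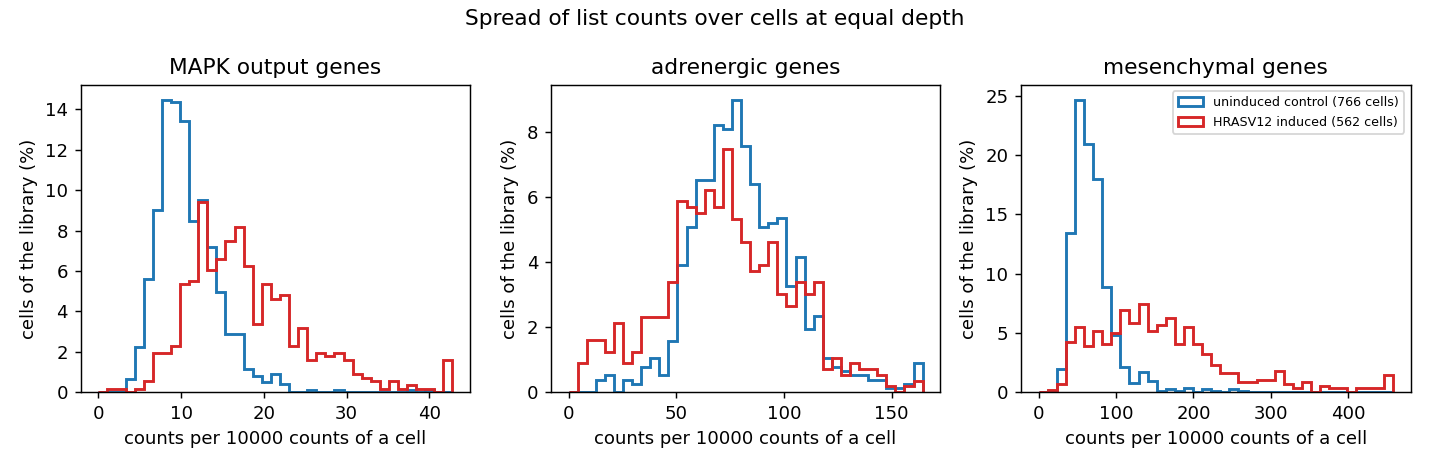
Share of the cells of each library (y axis, percent) by the counts per 10000 counts of a cell from the MAPK output, adrenergic and mesenchymal lists (x axes), for 562 induced (red) and 766 control cells (blue) thinned to 53000 counts, with cells beyond the right edge placed in the last bin. The median mesenchymal value was 142 in induced and 63.5 in control cells.

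Within the induced library, pooled mesenchymal counts differed by HRAS count. The intervals are of counts pooled over the cells of a bin and leave out the spread between cells. That spread was wide: induced cells ran from 46.5 to 325 mesenchymal counts per 10000 (5th to 95th percentile). Whether the bins differ beyond it was not tested. The 514 induced cells with at least 3 HRAS counts had 16315 CPM from the mesenchymal lists (16267 to 16363), the 31 with 2 had 11780 CPM (11614 to 11947), the 13 with 1 had 10997 CPM and the 4 with 0 had 12660 CPM. Without thinning, in bins of HRAS counts per 10000, the lowest bin of 51 cells had 15563 CPM, the next 13978 CPM, the third 16276 CPM and the highest 18284 CPM, which is no steady order. These bins are of another kind than the thinned ones, so the effect of thinning alone was not compared. In bins chosen after seeing the data, the 73 induced cells with 0 to 3 HRAS counts had 13743 CPM and the 182 with at least 10 had 17673 CPM. In the control library the same bins had 6886 CPM in 188 cells and 6594 CPM in 76 cells. Over the same 2 bins, MAPK output genes stood at 1681 and 1948 CPM in induced cells and at 1088 and 1015 CPM in control cells. The adrenergic lists stood at 8071 and 6698 CPM in induced cells and at 8136 and 7684 CPM in control cells, and without thinning the 4 induced bins had no steady order (6953, 7788, 7133 and 6378 CPM).

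**Figure D3:**
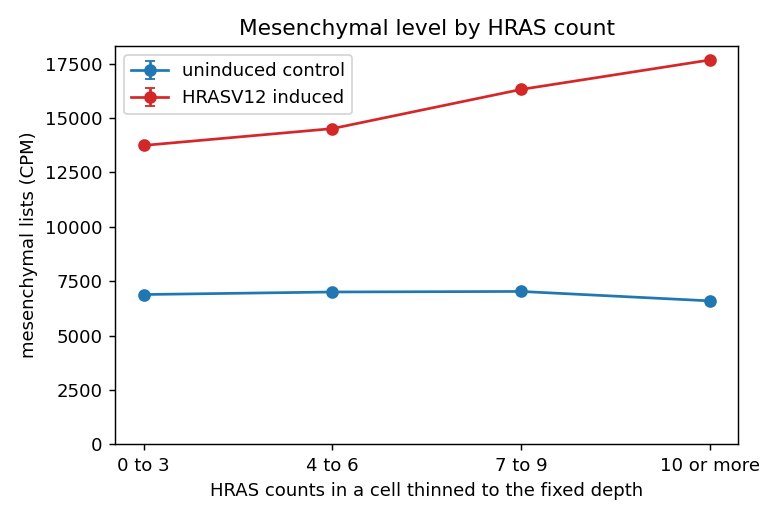
Pooled CPM of the mesenchymal lists (y axis) by the HRAS counts of a cell thinned to 53000 counts (x axis) in the HRASV12 induced (red) and uninduced control library (blue), with Poisson intervals as bars. The bars leave out the spread between cells. Induced cells ran from 13743 to 17673 CPM over the 4 bins.

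Genes of the cell cycle were lower in the induced library. Of 36 measured S phase genes, 31 were at least 1.5-fold lower and 0 higher by that size (median -0.88, 0th percentile of the random lists, and 24 of 36 lower with the limit on mitochondrial percent and MALAT1), with HELLS and ATAD2 the lowest and UBR7 and SLBP the highest. Of 52 G2 and M phase genes, 43 were at least 1.5-fold lower and 0 higher by that size (median -0.80, 0th percentile). TOP2A, a topoisomerase of dividing cells, stood at 119 against 293 CPM, NCAPD2 at 22.9 against 53.6 CPM, and RANGAP1 was near level at 42.9 against 45.1 CPM. Phase scores at equal depth placed 11.6% of induced cells (9.04 to 14.5) in S and 24.2% (20.7 to 28.0) in G2 or M, against 33.2% (29.8 to 36.6) and 45.4% (41.9 to 49.0) of control cells. Without thinning the shares were 11.1% and 26.6% against 29.7% and 46.5%. These calls rest on scores that free RNA can also reach. Among CDK inhibitors and senescence-associated genes, 5 of 12 were at least 1.5-fold higher and 0 lower by that size (median 0.52, 99.9th percentile). The median was 0.31 with the limit on mitochondrial percent and MALAT1 and 0.35 over the 4 genes of at least 50 CPM. IL11 stood at 12.5 against 3.17 CPM, while CDKN2A and CDKN1B were near level.

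ATF4 and amino acid response genes were higher in part, 7 of 20 by at least 1.5-fold and 0 lower by that size (median 0.42, 99.99th percentile). With totals that left out ribosomal protein and mitochondrial genes, 6 of 22 were higher and 1 was lower by that size, and with TMM scaling 10 of 20 were higher and 0 lower. DDIT3 stood at 124 against 29.5 CPM and TRIB3 at 52.7 against 12.4 CPM, while PSAT1 and ATF3 were the lowest. Mitochondrially encoded genes had a median of -0.45 (0.02th percentile), with MT-ATP8 and MT-ND3 lowest. The median was -0.03 with the limit on mitochondrial percent and MALAT1, but that limit picks cells by these same genes, so this value decides nothing. MYC and nucleolar genes had a median of -0.24 (0.54th percentile), with 3 of 23 at least 1.5-fold lower and CAD and FBL the lowest. Ribosomal protein genes had a median of -0.13 (0th percentile), with 0 of 78 past 1.5-fold either way, and 0.03 with DESeq2 size factors. Medians were -0.03 for endoplasmic reticulum chaperones (37.8th percentile), -0.16 for hypoxia and glycolysis genes (8.63th), 0.06 for cholesterol synthesis genes (74.5th) and -0.10 for heat shock and dissociation genes (16.6th). Each of these 4 medians, and those of the AP-1 family and the RAS pathway components, changed sign under at least 1 alternative scaling. Antigen presentation genes had a median of 0.38 over 5 members (95.6th percentile), with HLA-C at 60.1 against 28.7 CPM. NF-kB targets and interferon-stimulated genes had 3 measured members each, with medians of -0.36 (11.6th percentile) and -0.28 (18.9th).

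Markers of other cell types were mostly under the floor. No immune or erythroid marker reached 10 CPM. Of the Schwann cell precursor markers only PMP22 did, at 43.6 against 35.2 CPM. The endothelial markers EGFL7 and ESAM stood at 53.4 against 96.4 CPM and at 10.7 against 3.22 CPM, and 71.8% of the induced ESAM counts came from 52 induced cells of the cluster highest in these markers. In the next highest cluster, of 140 control and 6 induced cells, EGFL7 made up 199 of the 203 CPM of the list. KRT18 and KRT19, epithelial keratins, stood at 19.2 against 4.69 CPM and 17.0 against 12.6 CPM. Clustering of all 1622 cells gave 9 clusters, of which 5 had at least 90% of their cells from 1 library. With 1 library per group, such a cluster may be that library and not a cell type. No cluster reached 3 of the markers fixed for naming a cell type among its 10 leading genes, so none was named. Those markers left out many genes of the phase lists. The 10 leading genes of 1 cluster (167 control, 26 induced cells) included CENPE, NEK2 and AURKA of the G2 and M phase list. Those of another (316 control, 42 induced cells) included EXO1, BLM and PCNA of the S phase list. The cluster highest in the endothelial marker list was led by CD93, with EMCN and GIMAP4 also among its 10.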

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

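Of the scaling, cell and filter alternatives fixed in advance (11 for lists, 9 for HRAS) and the 2 chosen after seeing the data, none turned the HRAS ratio under 1 or the MAPK output, neuronal, mesenchymal surface, matrix, S phase or G2 and M phase medians to the other sign. TMM and DESeq2 scaling moved the median of all genes by 0.12 and 0.17 on the log2 scale, and list medians should be read against that shift. The HRAS ratio was 1.59 with TMM, 1.64 with DESeq2 size factors, 1.38 with totals without ribosomal protein and mitochondrial genes, 1.51 without the deepest cells, 1.53 after thinning and 1.39 with the limit on mitochondrial percent and MALAT1. Genes at least 2-fold higher numbered 643 with no filter and 133 at 50 CPM. Genes at least 2-fold lower numbered 65 with TMM, 47 with DESeq2, 211 with the smaller totals, 46 with a pseudocount of 5 CPM, 41 at 50 CPM and 44 with the limit on mitochondrial percent and MALAT1, which kept 406 induced and 871 control cells and shared 37 of those 44 genes with the 114. With TMM, medians were -0.69 for G2 and M phase, -0.25 for NF-kB, -0.016 for ribosomal protein and -0.34 for mitochondrially encoded genes. With DESeq2 they were -0.72 for S phase, -0.64 for G2 and M phase, -0.20 for NF-kB and -0.29 for mitochondrially encoded genes, and ribosomal protein genes turned to 0.032. With the smaller totals they were -0.22 for ribosomal protein and -0.040 for cholesterol synthesis genes. With the limit on mitochondrial percent and MALAT1 they were -0.71 for S phase, -0.27 for NF-kB, -0.27 for ribosomal protein and -0.035 for mitochondrially encoded genes. The last of these is shaped by the limit itself, which picks cells by those genes. Mesenchymal transcription factors were at -0.31 at 50 CPM (4 genes), NF-kB targets at -0.022 with no filter, and G2 and M phase genes at -0.71 with a pseudocount of 5 CPM. Mitochondrially encoded genes were at -0.33 without the deepest cells and at -0.33 after thinning. The matrix median, 1.33 over 11 genes in all cells, was 0.46 over 8 genes without the cells of the cluster highest in the endothelial marker list, and that of the mesenchymal transcription factors turned to -0.054. Filters and totals move counts by construction, and for the other values the cause was not tested. Induced cells above the control 95th percentile were 39.4% for MAPK output and 59.0% for mesenchymal genes when thinned to 26500 counts, and 33.3% for MAPK output without CCND1. Induced cells above the adrenergic median were 54.8% without DLK1. The induced minus control difference in cells called S or G2M was -42.8 percentage points, and -28.4 for cells with a TOP2A or MKI67 count. The HRAS bins of 4 and 13 induced cells are too thin to order.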

Other observations

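All tests in this part were chosen only after the results were seen. The following genes lie outside the lists, except CD44, and were picked after their values were seen, so they stand for no group. NPY, neuropeptide Y, stood at 1339 against 344 CPM and VIP, vasoactive intestinal peptide, at 274 against 69.4 CPM. TMSB4X and TMSB10, which bind actin monomers, stood at 1362 against 310 CPM and 3498 against 1003 CPM. HMOX1, heme oxygenase, stood at 42.7 against 4.93 CPM, with 73.7% of its induced counts in 180 induced cells of 1 cluster and a log2 ratio of 2.88 that was 1.46 with the limit on mitochondrial percent and MALAT1, and PPP1R15A, which acts in the stress response, at 73.1 against 18.8 CPM. CD44, a surface marker of mesenchymal cells, had 268 counts against 3, a ratio of 106 with a wide interval (35.9 to 517), and was under the 10 CPM floor. Its log2 ratio of 2.07 was 1.35 without the cells of the cluster highest in the endothelial marker list.

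The mesenchymal surface and cytoskeletal genes were higher in a library that also held more cells of low MALAT1 and fewer cycling cells. Both libraries were limited to cells at or above the control 5th percentile of mitochondrial percent and MALAT1. The median log2 ratio was then 0.86 (order-statistic interval over 22 genes 0.56 to 1.57), against 1.26 over 24 genes in all cells. ANXA1, at 5.20 CPM in the limited induced cells, fell under the floor, so the 2 medians are not of the same genes. The median of 0.86 argues against cells low in these 2 measures as the whole source. Among cells called G1 in both libraries, 361 induced and 164 control, the median was 1.15 (over 24 genes, 0.54 to 1.86), which argues against cycling alone. Doxycycline itself cannot be told apart from HRASV12, since 0 libraries of treated cells without the transgene were analysed here. A library difference also stays open with 1 library per group.

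Some cells carried endothelial genes. At equal depth 13 of 562 induced cells (2.31%, 1.24 to 3.92) and 7 of 766 control cells (0.914%, 0.368 to 1.87) had counts of at least 4 of the 10 endothelial markers. Without thinning these were 28 of 666 induced cells (4.20%) and 13 of 956 control cells (1.36%). EGFL7, 1 of the 10, was not particular to such cells. It stood at 199 CPM in the cluster of 140 control and 6 induced cells in which CARTPT was concentrated. 2 tests of free RNA were run on the cells at equal depth. The first, against a random spread of marker counts over cells (6.08% expected), decided nothing because counts held in few cells lower that share. In the second, the catecholamine and chromaffin genes of the 13 induced cells stood at 0.129 of their level in other induced cells (0.119 to 0.140). These levels are shares of a cell's counts, which added RNA lowers by dilution. Added RNA would reach 0.129 only if it made up most of the counts of these cells. The level also lies under 0.4, a bound for doublets with a neuroblastoma cell that was set after the results were seen. A doublet could still lie under that bound if the other cell held most of the RNA. MYCN stood at 2.60 times its level in other induced cells (2.45 to 2.75), against endothelial cells with low MYCN. HRAS stood at 0.557 of its level in other induced cells (0.459 to 0.669), which does not tell another line from cells with less transgene RNA. The intervals of these levels are of counts pooled over 13 cells and leave out the spread between cells. Another line with high MYCN stays open, as does a rare state of this line, a hypothesis whose levels here rest on 13 cells and that genotypes in the reads would decide.

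FOS, FOSB, EGR1 and BTG2 were lower in the induced library while FOSL1, HBEGF and DUSP6 were higher. The heat shock and dissociation list had a median log2 ratio of -0.10 (order-statistic interval over 14 genes -0.33 to 0.11), which argues against a heat shock response in the control cells. An immediate-early response during harvest was not tested and stays open, as does damping under lasting RAS signalling. Other immediate-early genes, picked after their values were seen, went both ways. JUN stood at 116 against 164 CPM and IER2 at 201 against 305 CPM. PPP1R15A, which also acts in the stress response, stood at 73.1 against 18.8 CPM. CCN1, a member of the matrix list under the 10 CPM floor, stood at 5.53 against 0.262 CPM.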
